A study of Mus musculus with 18 samples.

How the data were processed

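The series held 18 arrays of G1E-ER4 cells, a mouse erythroid line that lacks its own Gata-1 protein and carries Gata-1 joined to the hormone-binding part of the estrogen receptor (Gata-1-ER). Estradiol switches the fusion protein on. RNA was taken before treatment (0 h) and at 3, 7, 14, 21 and 30 h of estradiol, with 3 biological replicates, named A, B and C in the labels, at each time. Each sample was hybridized to 1 Affymetrix MG-U74Av2 array, a chip that reads each transcript with a probe set, a group of short DNA probes. The deposited values, per the labels, were signal intensity values on a linear scale, 1 for each probe set and array. The summary algorithm, the scaling target and the detection calls were not given in the sources used here. The 2% trimmed mean of every array lay between 149.949 and 149.958, so the arrays had been scaled to a common mean before they were deposited. No value was below 0 and 0 pairs of arrays were identical.

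The array held 12488 probe sets. The 66 control probe sets were left out and 12422 were tested. Of these, 10833 carried 1 gene symbol in the platform table, 396 carried several and 1193 carried none. By gene number, 10817 of the 10833 were found in the RefSeq gene table, and 0 symbols had to be changed. The symbols stood for 8251 genes, of which 2073 had more than 1 probe set. A gene was represented by its probe set with the highest mean log2 signal over the 18 arrays, among probe sets with exactly 1 symbol. Probe set names that end in _f_at, _s_at, _r_at, _i_at or _g_at mark probes that may read several related transcripts or that break a design rule, and the gene given for them is uncertain.

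A constant of 16 was added to each value, the log2 was taken and the arrays were quantile normalized. The linear model of limma was fitted to all 18 arrays with 1 mean for each time, which left 12 residual degrees of freedom. Moderated statistics came from eBayes with an intensity trend in the variance. Each later time was compared with 0 h, each time from 7 h on with the time before it, and an F test was run over all times. A probe set was called when its Benjamini-Hochberg adjusted p was below 0.05 within that comparison. All p values of single genes are adjusted p values of limma, and errors of log2 changes are standard errors (SE) of that model. Signals are means of 3 arrays on the deposited scale. Because the smallest possible p of an exact permutation of 3 against 3 arrays is 0.1, the gene tests rest on the variance shared across probe sets.

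The genes to be named were fixed by a rule before the data were examined. For 30 h against 0 h the rule took the 12 largest rises and the 12 largest falls among called genes in which all 3 arrays of 1 time lay beyond all 3 of the other. For 3 h against 0 h it took 8 and 8, and for each other comparison 4 and 4. From each gene list it took the 4 members with the smallest p in the F test over time, and it took Gata1 and Gata2 in every array. Other genes were named as members of the fixed lists, apart from those named for a high or low value at 14 h or for a return from 3 h to 7 h. Those were chosen after their values were seen.

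The 32 gene lists were also written before the data were examined. They were globins and globin chaperone, heme biosynthesis, iron uptake and handling, red cell membrane and skeleton, red cell enzymes, erythroid transcription factors, stem and progenitor regulators, megakaryocyte markers, mast cell and basophil markers, neutrophil and macrophage markers, lymphocyte markers, and fibroblast and stromal markers. Others were ribosome biogenesis, DNA replication, mitosis, cell cycle inhibitors, G1 cyclins and kinases, apoptosis regulators, autophagy and organelle clearance, nuclear condensation and late erythroid ubiquitin genes, cytokine receptor signalling, immediate early and dissociation genes, and heat shock and unfolded protein response. The remaining lists were interferon response, estrogen receptor target genes, glycolysis, cholesterol and lipid synthesis, ribosomal proteins, respiratory chain and ATP synthase, histones, proteasome, and aminoacyl tRNA synthetases. Each list was tested with camera of limma, which asks whether the members moved together more than the remaining genes, at a preset correlation of 0.01 between members. The p values were adjusted over the 160 tests of 32 lists at 5 times. Member calls were counted with the adjustment over all probe sets and again with the adjustment over the list alone.

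The alternatives chosen before the data were examined were the values without quantile normalization, scaling to a common median, constants of 1 and 64, the 33.3% of probe sets with the lowest mean left out, a model without the intensity trend, array quality weights, a block for the replicate letter, a model of the compared groups alone, and each array left out in turn. For the lists they were camera with an estimated correlation, fry, and the mean over all probe sets of a gene. An analysis without the arrays 14 h A and 21 h A was added after the arrays had been seen.

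The array median signals ran from 38.2 to 50.9. The 19 control probe sets for transcripts absent from mouse cells had medians from 4.2 to 15.6 on the arrays and a highest value of 52.9. Values under about 50 were therefore close to background. The correlation between replicates across the log2 values ran from 0.954 to 0.974, and between the 30 h and 0 h arrays from 0.870 to 0.886. The arrays 14 h A and 21 h A had the lowest quality weights, 0.601 and 0.572, and the lowest mean correlation with their replicates, 0.957 each.

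The analysis was tested on simulated data that had the 0 h means and the replicate spread of each of the 12422 probe sets. For 30 h against 0 h, 50 changes of each size were planted in probe sets above a signal of 100. It called 8% of the planted changes of 0.5 log2 units, 72% of those of 1, and 100% of those of 2 and of 3. Among the 12222 probe sets without a planted change, 7 were called. In this simulation changes below 1 log2 unit were thus often left uncalled with 3 arrays for each time. Far fewer probe sets changed in it than the 3314 called at 30 h in the data. The Benjamini-Hochberg cut is stricter when few probe sets change, so these shares do not carry over to that comparison. Small changes can still have been missed there, at a rate that was not measured. The work was done in R 4.3.3 with limma 3.58.1, and in Python 3.11.15 with matplotlib 3.10.9.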

Results

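G1E-ER4 cells are mouse erythroid progenitors that were derived from embryonic stem cells without a working Gata1 gene. Gata-1 is the transcription factor that red cell precursors need in order to mature. The cells do not complete this step by themselves and carry a Gata-1-ER fusion, which estradiol makes active. The labels describe 18 arrays, with 3 biological replicates (A, B, C) each of untreated cells and of cells at 3, 7, 14, 21 and 30 h of estradiol. The comparisons therefore address which transcripts differed from untreated cells at each time after Gata-1-ER was switched on, and which differed between neighbouring times. Among the 18 arrays there was none of estradiol-treated cells without the fusion and none of untreated cells kept to a later time. Sizes are log2 changes after a constant of 16 had been added, so the changes of dim genes are understated. Signals are means of 3 arrays, n = 3 at every time.

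After 3 h, Csf2rb, the shared receptor chain for interleukin 3, interleukin 5 and GM-CSF, rose from a signal of 32.1 to 515 (log2 change 3.50, SE 0.32, adjusted p = 2.89e-06). Uhrf1bp1, named for a protein that binds Uhrf1, rose from 193 to 773 (1.96, SE 0.14, adjusted p = 1.28e-07). Rogdi, a leucine zipper gene altered in a human seizure and enamel syndrome, rose from 126 to 506, and Gtf2b, which codes for the general transcription factor TFIIB, from 410 to 1433 (1.88 and 1.85, adjusted p = 1.12e-06 for each). Pfkm, the muscle form of phosphofructokinase, went up by 1.62 (SE 0.18), Tbc1d15, which acts on the vesicle GTPase Rab7, by 1.59 (SE 0.20), and Specc1, a coiled-coil gene, by 1.81 (SE 0.30). Bach1, a repressor that is released from DNA by heme, rose by 1.88 (SE 0.36, adjusted p = 0.00922). Its call was lost without array 3 h A (1.60, adjusted p = 0.0791) and without 3 h B (1.76, adjusted p = 0.0600).

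Among the transcripts that fell by 3 h was Gata2, the Gata factor of stem and early progenitor cells, from 1909 to 454 (−2.20, SE 0.23, adjusted p = 1.7e-05). The largest fall under the naming rule was that of Nab2, a corepressor of the Egr factors, from 681 to 72.7 (−2.91, SE 0.32, adjusted p = 2.61e-05). Jund, a member of the AP-1 transcription factors, fell from 1366 to 281 (−2.34, SE 0.33). Cbfa2t3, the corepressor also called Eto2 that binds Tal1 complexes, dropped from 351 to 57.1 (−2.28, SE 0.18). Lyl1, a close relative of Tal1, fell from 3506 to 793 (−2.25, SE 0.18, adjusted p = 4.54e-07). Adgrg1, an adhesion receptor of stem cells, changed by −1.69 (SE 0.24). Il4ra, the interleukin 4 receptor chain, fell from 143 to 22.3, and Mnt, which opposes Myc, from 114 to 16.7 (−1.94, SE 0.36). Without array 3 h B these calls were lost (Il4ra −1.74, adjusted p = 0.0652; Mnt −1.78, adjusted p = 0.0516). Members of the fixed lists that were called at 3 h included Zfpm1, the Gata-1 partner Fog-1 (0.84), Klf1, a red cell factor (0.47), Tal1 (−1.45), the immediate early gene Ier2 (−1.48) and the replication licensing gene Cdc6 (0.82). In the limma test of 12422 probe sets, 132 were called, 94 higher and 38 lower. Without array 0 h B the count was 87 and without 3 h A it was 77.

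By 7 h, Csf2rb stood at 1467 (4.98, SE 0.32, adjusted p = 1.28e-08). Ptdss2, which makes phosphatidylserine, rose from 90.5 to 919 (3.20, SE 0.12, adjusted p = 3.63e-12), and Rogdi to 1198 (3.16, SE 0.16). Csf2rb2, the interleukin 3 receptor chain that is nearly identical in sequence to Csf2rb, rose from 62.2 to 569 (2.79, SE 0.32). Dmtn, the actin-bundling protein dematin of the red cell skeleton, was up by 2.65, Ache, the acetylcholinesterase that red cells carry on their surface, by 2.77, and Alas2, the first enzyme of red cell heme synthesis, by 1.87. Tspan4, a tetraspanin membrane gene, fell from 296 to 25.8 (−2.94, SE 0.26, adjusted p = 6.26e-07), Gata2 to 338 (−2.56), Nab2 to 114 (−2.39) and Lyl1 to 765 (−2.29). In total 518 probe sets passed, 308 higher and 210 lower.

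At 14 h the largest rises under the rule were those of Csf2rb to 3332 (6.17, SE 0.32), Csf2rb2 to 2577 (5.02, SE 0.32), Dmtn from 27.0 to 1066 (4.63, SE 0.21, adjusted p = 2.28e-11) and Alas2 from 108 to 2365 (4.30, SE 0.22, adjusted p = 1.57e-10). Lyl1 fell to 209 (−4.10, SE 0.18), Gata2 to 142 (−3.71, SE 0.23), Tspan4 to 8.47 (−3.68, SE 0.26) and Nab2 to 54.1 (−3.30, SE 0.32). Myb, which keeps blood progenitors dividing, fell by 3.29, Kit, the receptor for stem cell factor, by 2.30, and Myc by 2.08. The test called 1655 probe sets, 814 higher and 841 lower.

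Alas2 had reached 7183 at 21 h (5.82, SE 0.22, adjusted p = 1.18e-12), Csf2rb 5055 (6.64, SE 0.32), Csf2rb2 5485 (6.03, SE 0.32) and Dmtn 1749 (5.26, SE 0.21). Slc4a1, the band 3 anion exchanger of the red cell membrane, was up by 4.90. The largest falls were those of Myb (−5.49, SE 0.29, adjusted p = 8.77e-11), Lyl1 (−5.02, SE 0.18), Mtm1, the lipid phosphatase myotubularin, from 4082 to 135 (−4.80, SE 0.19), and Lgals9, the sugar-binding protein galectin 9, from 987 to 29.7 (−4.73, SE 0.34). At this time 2571 probe sets were called, 1211 higher and 1360 lower.

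By 30 h, genes of the mature red cell stood among the largest rises. Alas2 rose from 108 (SD 15.3) to 12476 (SD 758), a log2 change of 6.69 (SE 0.22, adjusted p = 9.7e-14). Slc4a1 rose from 66.7 to 3652 (5.40, SE 0.37, adjusted p = 1.37e-09), Ache from 27.4 to 1730 (5.32, SE 0.31), and Dmtn to 1138 (4.67, SE 0.21). Csf2rb rose to 4980 and Csf2rb2 to 7857 (6.66 and 6.67, SE 0.32 each, adjusted p = 1.3e-11). Rogdi reached 5402 (5.24, SE 0.16), Bach1 1030 (4.43, SE 0.36) and Hebp1, a heme-binding protein, 2228 (3.93, SE 0.15). Btn1a1, a membrane protein best known from milk fat droplets, rose from 7.37 to 685 (4.90, SE 0.27), Wdr92, a WD repeat gene, from 537 to 12056 (4.49, SE 0.22), and Ddt, the enzyme D-dopachrome tautomerase, from 175 to 3132 (4.01, SE 0.15).

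The falls at 30 h included transcription factors of progenitors and genes of dividing cells. Myb dropped from 1346 to 7.47 (−6.00, SE 0.29, adjusted p = 1.41e-11) and Lyl1 from 3506 to 59.1 (−5.65, SE 0.18, adjusted p = 5.64e-14). Car1, carbonic anhydrase 1, fell from 3604 to 64.2 (−5.60, SE 0.18), and Lgals9 to 12.7 (−5.21, SE 0.34). Cdca7, a gene induced by Myc, fell from 1165 to 43.3 (−4.37, SE 0.21), Uhrf1, which keeps DNA methylation through replication, from 1585 to 87.7 (−4.09, SE 0.27), and Cdk1, the kinase that starts mitosis, from 947 to 50.3 (−4.08, SE 0.30). Genes of ribosome production were Tsr1, a maturation factor of the small subunit (−4.10, SE 0.24), and Gar1, a protein of the particles that modify ribosomal RNA (2735 to 164, −3.97, SE 0.20). Srm, which makes the polyamine spermidine, fell by 4.36 (SE 0.35), and Nefh, a neurofilament gene, by 4.22 (SE 0.28). Mtm1 fell from 4082 to 66.7 (−5.71, SE 0.19), whereas its other probe set rose from 40.3 to 81.3 (0.84), so which transcript fell is uncertain. Probe sets of the uncertain kinds also read Alas2, Myb, Lyl1 and Srm. Another probe set for Lyl1 gave −6.16, while the other one for Csf2rb2 was near background.

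The 30 h test called 3314 probe sets, 1594 higher and 1720 lower, of which 783 and 1074 differed at least 2-fold. These stood for 1289 genes higher and 1423 lower, with 21 genes in both because their probe sets differed in direction. In 3240 of the 3314 the arrays of the compared times did not overlap. A call from these same arrays nearly brings such separation with it, so this count is no separate support. Over all 6 times the F test called 3376 probe sets, 27.2% of those tested, for 2769 genes.

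**Figure D1:**
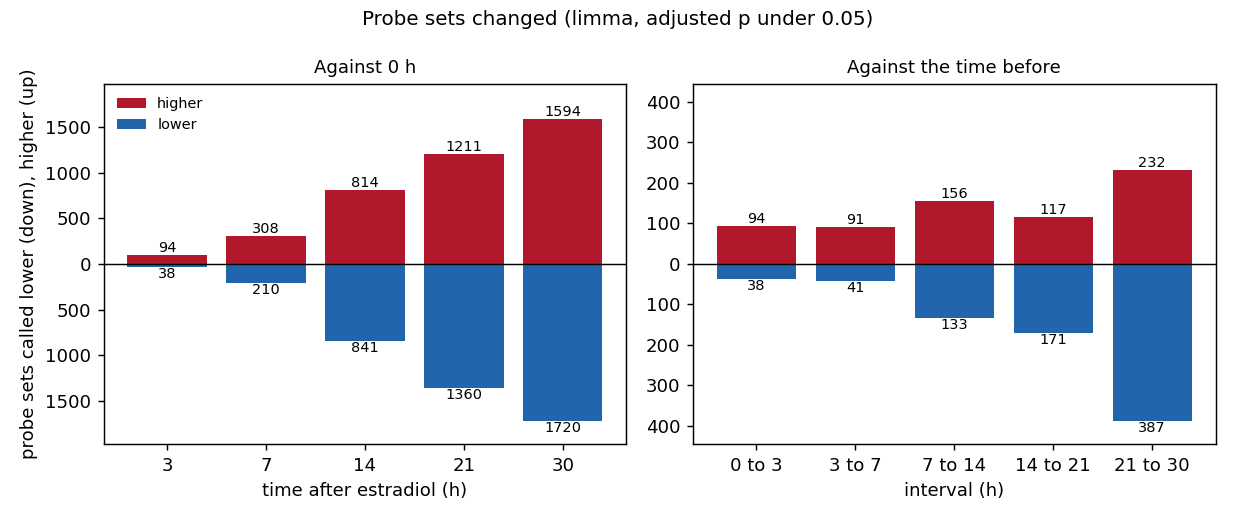
Number of probe sets called at adjusted p below 0.05 (vertical axis, count) in each comparison of times (horizontal axis), with 1 bar for those higher and 1 for those lower. Against 0 h both bars grow from 3 h to 30 h.

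Gata1 and Gata2 differed in course. Gata2 signals were 2092, 1940 and 1696 at 0 h, 402, 611 and 350 at 3 h, 352, 275 and 389 at 7 h, 175, 127 and 123 at 14 h, 179, 83.6 and 113 at 21 h, and 112, 85.6 and 137 at 30 h (−3.96 at 30 h, SE 0.23, adjusted p = 1.55e-10). Gata1 signals were 201, 157 and 269 at 0 h, 126, 150 and 136 at 3 h (−0.50, adjusted p = 0.481), 165, 221 and 207 at 7 h, 334, 204 and 217 at 14 h, 341, 428 and 470 at 21 h, and 480, 605 and 418 at 30 h. Gata1 was called higher at 21 h (1.02) and at 30 h (1.29, SE 0.21, adjusted p = 6.76e-05). The other Gata1 probe set, of an uncertain kind, rose less, from 132, 111 and 96.6 at 0 h to 172, 189 and 218 at 30 h. The other Gata2 probe set lay at background on all arrays, between 0.9 and 20.2, and could not show a fall. Whether the Gata1 probes also read the Gata-1-ER transcript was not tested.

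**Figure D2:**
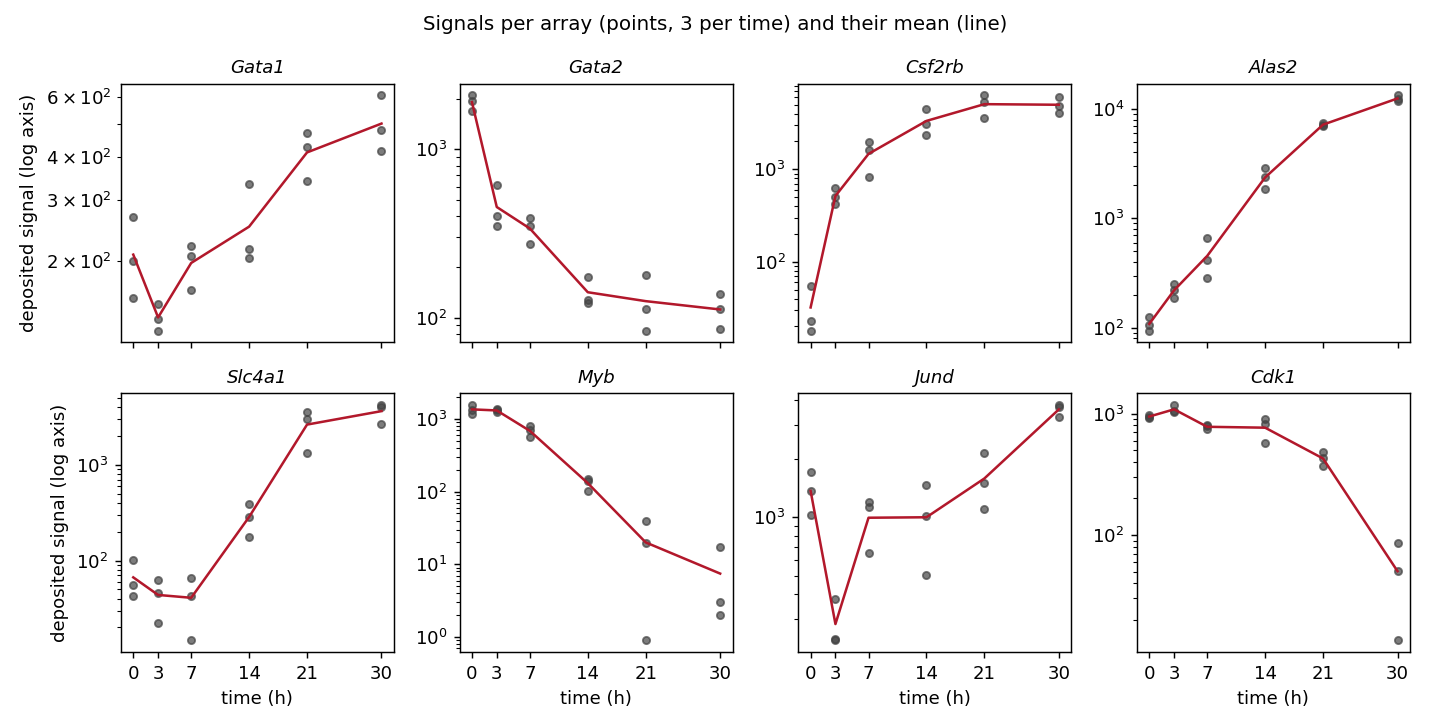
Signal (vertical axis, log scale, deposited units) of Gata1, Gata2, Csf2rb, Alas2, Slc4a1, Myb, Jund and Cdk1 against hours of estradiol (horizontal axis). Each point is 1 array and the line joins the means of 3; Gata2 is low from 3 h on, whereas Cdk1 is low at 30 h.

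From 3 h to 7 h, Ache rose from 24.7 to 272 (2.71, SE 0.31, adjusted p = 0.000148), Dmtn from 33.6 to 260 (2.38, SE 0.21), Ptdss2 by 1.94 (SE 0.12) and Jund from 281 to 994 (1.82, SE 0.33). Falls were those of Tspan4 (−1.83, SE 0.26), Clec4d, a lectin receptor of myeloid cells (−1.57, SE 0.30), Rcc1, the exchange factor of the nuclear GTPase Ran (−1.14, SE 0.21), and Fut8, which adds fucose to glycoproteins (−1.06, SE 0.22). The Jund call was lost without 3 h B (adjusted p = 0.0511), 3 h C (adjusted p = 0.0628) or 7 h A (adjusted p = 0.0524), that of Clec4d without 3 h C (adjusted p = 0.0758) or 7 h A (adjusted p = 0.0649), that of Rcc1 without 3 h A (adjusted p = 0.0620), 3 h C (adjusted p = 0.0770) or 7 h C (adjusted p = 0.0546), and that of Fut8 without any array of these times but 7 h C (adjusted p from 0.0519 to 0.125). Called were 132 probe sets, 91 higher and 41 lower; with median scaling 31 were higher and 27 lower. The count fell whichever array of these times was left out, so it did not rest on 1 particular array. Each such fit also had fewer arrays to compare. The count was 59 without 3 h A, 68 without 3 h B and 52 without 3 h C. Without 7 h A, 7 h B or 7 h C it was 73, 49 and 80.

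From 7 h to 14 h, Slc4a1 rose from 40.8 to 286 (2.49, SE 0.37, adjusted p = 0.000822), Alas2 from 453 to 2365 (2.43, SE 0.22), Csf2rb2 by 2.23 (SE 0.32) and Dmtn by 1.98 (SE 0.21). Rangrf, a partner of Ran in nuclear transport, fell from 186 to 17.1 (−2.58, SE 0.36), Myb from 682 to 131 (−2.27, SE 0.29), Lyl1 by 1.81 (SE 0.18) and the immediate early factor Egr1 by 1.87 (SE 0.46, adjusted p = 0.0360). The Egr1 call was lost without any array of these times but 7 h A (adjusted p from 0.0809 to 0.165). Of 289 probe sets called, 156 were higher and 133 lower. The count was 180 without 7 h A, 160 without 7 h C and 140 without 14 h A.

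From 14 h to 21 h, Slc4a1 rose again, from 286 to 2640 (3.01, SE 0.37, adjusted p = 0.000165), as did Alas2 (1.52, SE 0.22). Mt2, a metal-binding metallothionein, rose from 2586 to 7796 (1.53, SE 0.22), and Padi2, which turns arginine of proteins into citrulline, from 21.2 to 72.9 (1.33, SE 0.34), with its call lost without any 1 of the 6 arrays (adjusted p from 0.0959 to 0.128). Lgals9 fell by 2.45 (SE 0.34), Pold2, a subunit of the replicating DNA polymerase delta, from 433 to 62.7 (−2.44, SE 0.17), Myb by 2.20 (SE 0.29) and Mtm1 by 2.13 (SE 0.19). The test called 288 probe sets, 117 higher and 171 lower, and with median scaling 102 higher and 70 lower. Without 14 h B it called 165, without 14 h C 119 and without 21 h A 156.

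From 21 h to 30 h, genes of mitosis fell: Kif20a, a kinesin motor of the late spindle, from 680 to 66.2 (−3.13, SE 0.23, adjusted p = 8.98e-08), Cdk1 from 427 to 50.3 (−2.93, SE 0.30), Top2a, the topoisomerase that untangles chromosomes, from 513 to 68.8 (−2.66, SE 0.23), and Aspm, a spindle pole gene, from 131 to 9.30 (−2.61, SE 0.28). Hbb-y, an embryonic beta globin, rose from 47.8 to 351 (2.63, SE 0.41), Ninj1, an adhesion gene of the cell surface, from 14.9 to 113 (2.06, SE 0.29), and Tmem150a, a membrane gene, from 152 to 564 (1.77, SE 0.28). Snrp1c-ps2, a pseudogene of a splicing protein, rose by 1.79 (SE 0.31). The probe sets of Kif20a, Hbb-y and Snrp1c-ps2 were of the uncertain kinds. There were 619 called probe sets, 232 higher and 387 lower, and 402 without array 21 h B.

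Among the fixed lists, that of globins and globin chaperone had 5 measured members. Hba-a1, the adult alpha globin, rose from 6061 to 26549 by 30 h (1.87), the adult beta globin Hbb-b2 from 1435 to 10904 (2.87), and the embryonic globins Hbb-y by 3.30, Hba-x by 2.52 and Hbb-bh1 by 1.72. Globin probe sets can read more than 1 member of the family. At 30 h 5 of 5 were higher, 5 when adjusted over the list alone, with a median of 2.52 (camera adjusted p = 0.000110; adjusted p = 0.0490 with an estimated correlation). At 14 h 2 were higher, 4 when adjusted over the list alone (adjusted p = 0.000775; adjusted p = 0.0892 with an estimated correlation), and at 21 h 4, again 4 when adjusted over the list alone (adjusted p = 0.000858; adjusted p = 0.0892 with an estimated correlation).

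Genes of heme biosynthesis were called higher from 7 h on. Besides Alas2, those that rose by 30 h were Urod (610 to 2751, 2.03), Abcb10, a mitochondrial transporter (2.04), Ppox (200 to 749, 1.91), Alas1, the form of other tissues (1.62), Alad (1352 to 4362), Fech (0.95) and Uros (0.94). Cpox stood at −0.47 and was not called. The list of 9 had 4 higher at 7 h, 7 at 14 h, 7 at 21 h and 8 at 30 h, and adjusted over the list alone 6, 7, 7 and 8. Medians were 0.66, 1.59, 1.78 and 1.62, with adjusted p = 2.5e-05, 1.78e-08, 7.26e-08 and 7.65e-06 in the camera test. Under iron uptake and handling, the transferrin receptor Tfrc was higher at 21 h (1.28) and the ferritin chain Fth1 at 30 h (0.54). At 30 h 1 of 8 was called, 1 when adjusted over the list alone, with a median of 0.35 (adjusted p = 0.442).

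In the list of red cell membrane and skeleton, Slc4a1 and Dmtn were joined by Mpp1, the p55 protein (889 to 5517, 2.52), Add1, the alpha chain of adducin (2.20), Tspan33 (2.13) and Ank1, the ankyrin that ties band 3 to spectrin (967 to 3651, 1.76). Bsg (−1.42), which chaperones lactate carriers, and Rhag (−1.01), the Rh-associated glycoprotein, fell by 30 h. Of 14 members 6 were higher and 2 lower at 30 h, 7 and 2 when adjusted over the list alone, with a median of 0.52 (adjusted p = 0.00360; adjusted p = 0.0892 with an estimated correlation). At 7 h 5 were higher, 5 when adjusted over the list alone (adjusted p = 0.00529; adjusted p = 0.104 with an estimated correlation). At 14 h and 21 h 7 were higher, 7 when adjusted over the list alone beside 1 lower at 14 h, with adjusted p = 7.85e-06 and 3.23e-05. Red cell enzymes moved both ways. Prdx2, an abundant peroxide-removing enzyme of red cells, rose from 3386 to 11535 (1.63), Car2 by 0.84, Bpgm by 0.78 and Cat by 0.66, while Car1, Txn1 (−1.71) and Gsr (−1.47) fell. At 30 h 4 of 16 were higher and 3 lower, 4 and 4 when adjusted over the list alone; the median was 0.18, the mean −0.28 and the camera direction down (adjusted p = 0.996). At 21 h the median was 0.21, the mean −0.12 and the direction up.

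Erythroid transcription factors called higher at 30 h were Mafk, a small Maf partner of Nfe2 (197 to 939, 2.19), Zfpm1 (1893 to 7381, 1.82), Klf3 (1.60), Gata1, Foxo3 (1.16), Nfe2 (1.10), Klf1 (0.90) and Mafg (0.82). Lyl1 and Sox6 (−0.72) were lower, although Sox6 lay near background. Gfi1b, a repressor needed for red cell formation, was higher at 7 h (1.32) and 14 h (0.76), and Lmo2, a bridge between Tal1 and Gata-1, at 7 h (0.94) and 14 h (0.73). Of 16 members 8 were higher and 2 lower at 30 h, 8 and 2 when adjusted over the list alone, with a median of 0.51 (adjusted p = 0.0584). At 14 h 6 were higher and 1 lower, 7 and 1 when adjusted over the list alone (adjusted p = 0.0154; adjusted p = 0.128 with an estimated correlation). At 21 h it was 7 and 1, also 7 and 1 when adjusted over the list alone (adjusted p = 0.0138; adjusted p = 0.127 with an estimated correlation).

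Stem and progenitor regulators that fell by 30 h were Myb, Gata2, Kit (447 to 26.4, −3.55), Myc (250 to 9.70, −3.36), the homeobox factor Hhex (−1.78), Id1 (−0.74), Hes1 (−0.57) and Egr1. Egr1 stood at −1.30 and its call was lost without 0 h B (−1.02, adjusted p = 0.180), 0 h C (−1.01, adjusted p = 0.186), 30 h A (−1.17, adjusted p = 0.127), 30 h B (−1.33, adjusted p = 0.0801) or 30 h C (−1.39, adjusted p = 0.0698). Spi1, the myeloid factor PU.1 that opposes Gata-1, rose from 157 to 263 (0.81). At 30 h 1 of 21 was higher and 8 lower, 2 and 8 when adjusted over the list alone, with a median of −0.24 and a mean of −0.96 (adjusted p = 0.0311; adjusted p = 0.365 with an estimated correlation; 0.0509 without 30 h A). At 3 h 1 was lower, 2 when adjusted over the list alone (adjusted p = 0.0293; adjusted p = 0.362 with an estimated correlation; 0.0871 without 0 h B and 0.0949 without 3 h A). At 14 h 1 was higher and 7 lower, 3 and 8 when adjusted over the list alone (camera adjusted p = 0.0426). The camera adjusted p at 14 h was 0.402 with an estimated correlation, 0.0669 without 0 h B, 0.189 without 14 h B and 0.0622 with a replicate block. At 21 h 8 were lower, 8 when adjusted over the list alone beside 1 higher (adjusted p = 0.0278; adjusted p = 0.362 with an estimated correlation; 0.0686 without 21 h B). Cd34 and Hoxa10 lay near background.

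Of 11 megakaryocyte markers, Gp9, a platelet glycoprotein, was higher at 14 h (30.8 to 118, 1.46) and 21 h (1.34) but stood at −0.20 at 30 h, when 0 of 11 were called with limma, 0 when adjusted over the list alone (adjusted p = 0.957). Of 16 mast cell and basophil markers, the mast cell protease Cma1 rose by 1.68 by 30 h, and Mcpt1 (−1.32) and Ndst2 (−1.44), which makes heparin in mast cells, fell; Cma1 (9.73 to 64.2) and Mcpt1 (53.3 to 12.6) lay close to background. The count was 1 higher and 3 lower, also 1 and 3 when adjusted over the list alone (adjusted p = 0.534). The third lower member was Cpa3 (−0.70), a mast cell protease near background at every time, whose call was lost without 0 h A (adjusted p = 0.134), 0 h C (adjusted p = 0.126), 30 h A (adjusted p = 0.138) or 30 h B (−0.76). Of 24 neutrophil and macrophage markers, 4 were higher at 30 h, 4 when adjusted over the list alone (median 0.40, adjusted p = 0.103). These were Camp, an antimicrobial peptide (1.49), the adaptor Tyrobp (4.63 to 26.1, near background), the iron-binding secreted protein Lcn2 (0.87) and the Fc receptor Fcgr3 (0.81, near background; 0.64 without 30 h C, adjusted p = 0.0601).

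Of 22 lymphocyte markers, the B cell genes Ms4a1 (1.02) and Pax5 (0.93) were higher at 30 h, 0 when adjusted over the list alone (list median 0.07, adjusted p = 0.755). The Ms4a1 call was lost without 0 h C (adjusted p = 0.104) or 30 h C (adjusted p = 0.0557). The Pax5 call was lost without 0 h B (adjusted p = 0.134), 0 h C (adjusted p = 0.0843), 30 h B (adjusted p = 0.106) or 30 h C (adjusted p = 0.204). Of 20 fibroblast and stromal markers, Vim, the intermediate filament vimentin, was higher (0.83), 0 when adjusted over the list alone (list median −0.07, adjusted p = 0.911). The estrogen receptor target genes, 14 measured, had 0 called at 3 h with limma and 2 lower when adjusted over the list alone (median −0.13, adjusted p = 0.0735). At 7 h 1 was lower, 2 when adjusted over the list alone (median −0.21, camera adjusted p = 0.0817). At 30 h the lysosomal protease Ctsd (1.60) and the growth factor Igf1 (1.34) were higher, and the vessel growth factor Vegfa (−1.88) was lower. The split was 2 higher and 4 lower, 2 and 4 when adjusted over the list alone (median 0.30, adjusted p = 0.736). The fry test asks whether members moved, without comparing them with the remaining genes. It put this list lower at 3, 7 and 14 h (fry adjusted p = 0.0106, 0.00179 and 0.0486) and higher at 30 h (fry adjusted p = 0.0156).

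Genes of ribosome biogenesis were called lower from 7 h on. By 30 h Gar1 was followed by Nop58, a core protein of RNA-modifying particles (541 to 33.7, −3.48), Rrs1 (843 to 79.5, −3.15), Nop16 (755 to 81.9, −2.98), Fbl, the methylase fibrillarin (3057 to 553, −2.52), and the abundant nucleolar proteins Npm1 (6350 to 1869, −1.91) and Ncl (8433 to 2572, −1.85). Rrn3, a starting factor of ribosomal RNA synthesis, rose (0.60). Of 29 members 10 were lower at 7 h, 21 at 14 h, 26 at 21 h and 26 at 30 h, and adjusted over the list alone 16, 26, 26 and 27. Rrn3 was the 1 called higher at 30 h, and adjusted over the list alone 1 was higher at 7 h and 1 at 30 h. Medians were −0.55, −1.07, −1.90 and −2.25. The camera test gave adjusted p = 2.33e-10 at 7 h (adjusted p = 0.110 with an estimated correlation), 2.7e-18 at 14 h, 5.78e-21 at 21 h and 1.64e-18 at 30 h. Of the 35 ribosomal proteins 6 were lower at 30 h, 4 when adjusted over the list alone (median −0.14, adjusted p = 0.151), led by Rpl22 (−1.17) and Rpl13a (−0.97).

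DNA replication genes had few calls up to 14 h and fell after it. By 30 h the nucleotide enzyme Rrm2 had fallen from 1234 to 78.0 (−3.88), the helicase part Mcm4 from 983 to 61.2 (−3.76), the loading factor Cdt1 from 1140 to 73.4 (−3.72), Pold2 by 3.74 and the sliding clamp Pcna from 1414 to 135 (−3.26). Of 35 members 23 were lower and 1 higher at 21 h, 25 and 1 when adjusted over the list alone (median −0.90, adjusted p = 6.2e-08; adjusted p = 0.362 with an estimated correlation). At 30 h 32 were lower, 33 when adjusted over the list alone (median −2.18, adjusted p = 2.27e-20; adjusted p = 0.108 with an estimated correlation). Cdc6 was the 1 higher at 3 h, 1 when adjusted over the list alone (list median 0.13, adjusted p = 0.0124; adjusted p = 0.747 with an estimated correlation; 0.0746 without 0 h A and 0.0557 without 3 h C).

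Some mitosis genes were called higher at 7 h and 14 h, and most were called lower at 30 h. The kinase Plk1 was at 0.60 and 0.77 at 7 h and 14 h, Ccnb2, cyclin B2, at 0.95 and Top2a at 0.88 at 14 h, all called higher. By 30 h Plk1 (−1.40), Ccnb2 (1723 to 572, −1.69), Top2a (−2.25), Kif20a (−2.98) and the checkpoint gene Mad2l1 (631 to 65.9, −3.04) had fallen. Of 31 members 4 were higher at 7 h and 11 at 14 h, 5 and 13 when adjusted over the list alone (medians 0.30 and 0.51, adjusted p = 0.000329 and 0.000110; adjusted p = 0.578 and 0.514 with an estimated correlation). At 3 h 0 were called with limma, 1 when adjusted over the list alone, at a median of 0.20 (adjusted p = 3.23e-05; adjusted p = 0.453 with an estimated correlation). At 21 h 5 were higher and 4 lower, 7 and 5 when adjusted over the list alone. At 30 h 27 were lower, 27 when adjusted over the list alone (median −1.77, adjusted p = 6.04e-16; adjusted p = 0.110 with an estimated correlation).

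**Figure D3:**
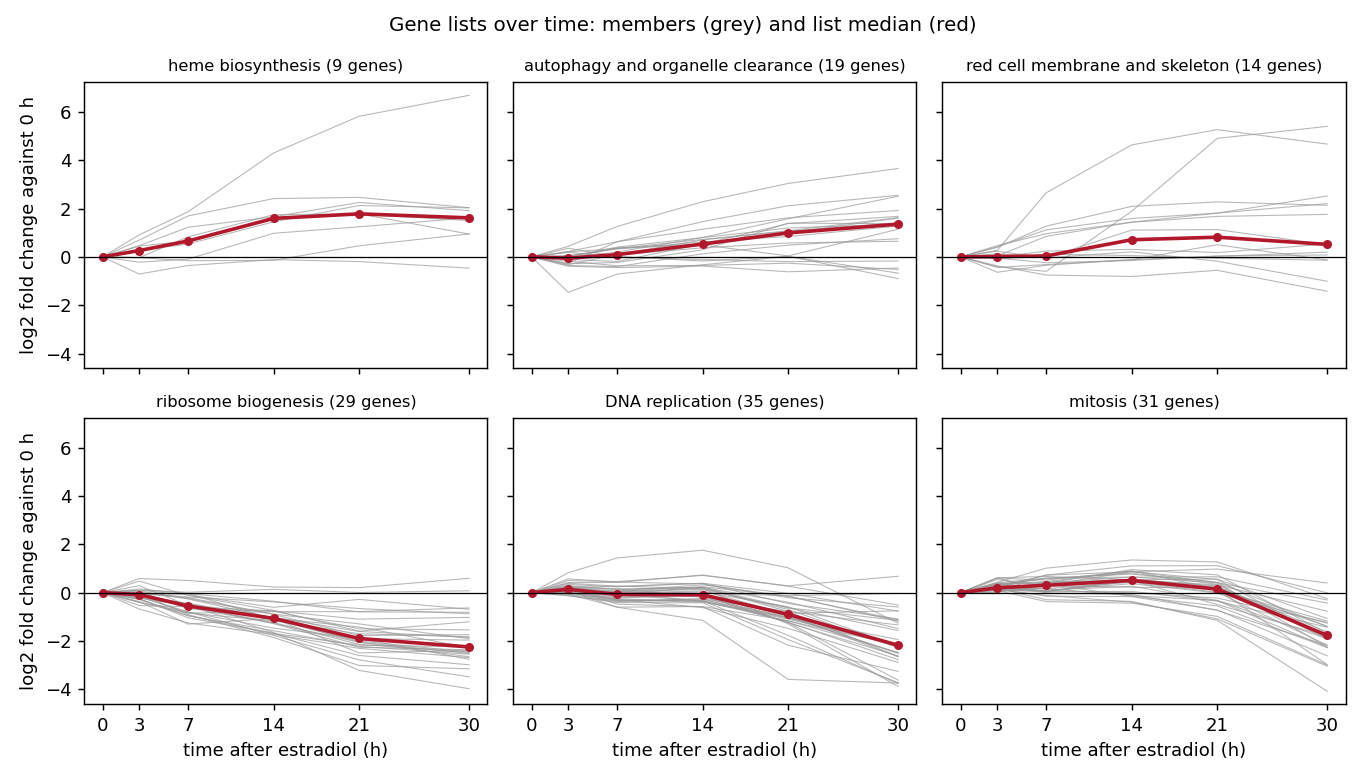
Log2 change against 0 h (vertical axis) by hours of estradiol (horizontal axis) for 6 fixed lists, with members as grey lines and their median in red. At 7 h the median of heme is 0.66 and that of ribosome biogenesis −0.55, that of autophagy reaches 0.53 at 14 h, and those of DNA replication and mitosis are −2.18 and −1.77 at 30 h.

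Several cell cycle inhibitors were called higher. Btg2, which slows division, went from 292 to 3214 by 30 h (3.35), Mxd1, a Max partner that opposes Myc, was up by 2.90, the stress genes Gadd45g and Gadd45a by 2.58 and 2.23, and the kinase inhibitors Cdkn2c, Cdkn1b and Cdkn1a by 2.03, 1.89 and 0.99. Rbl1, the p107 pocket protein, fell (−1.88). Of 22 members 10 were higher and 1 lower at 30 h, 11 and 1 when adjusted over the list alone (median 0.79, adjusted p = 0.00604; adjusted p = 0.128 with an estimated correlation). At 7 h 4 were higher, 4 when adjusted over the list alone (adjusted p = 0.0154; adjusted p = 0.181 with an estimated correlation; 0.0818 without 0 h B and 0.0668 without 7 h C). At 14 h 7 were higher and 1 lower, 8 and 1 when adjusted over the list alone (adjusted p = 0.00698; adjusted p = 0.134 with an estimated correlation). At 21 h 8 were higher and 2 lower, 9 and 3 when adjusted over the list alone (adjusted p = 0.00680; adjusted p = 0.134 with an estimated correlation). Among G1 cyclins and kinases, Tfdp1, the partner of the E2f factors (1070 to 122, −2.96), Myc, Cks1b (−1.58), Cdk4 (−1.34) and Ccnd2 (−1.32) fell, and Ccnd3, the cyclin D3 of red cell precursors, rose from 925 to 2284 (1.12). At 30 h 1 of 13 was higher and 7 lower, 2 and 9 when adjusted over the list alone (median −0.81, adjusted p = 0.00371).

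Autophagy and organelle clearance genes were called higher mostly from 14 h. By 30 h the lysosomal protease Ctsb had risen from 347 to 4733 (3.66), the autophagosome proteins Map1lc3b from 320 to 2014 (2.55) and Gabarap from 1188 to 7351 (2.51), the lysosomal membrane protein Lamp1 from 2905 to 9723 (1.63) and Ctsd from 1022 to 3399 (1.60). Tfeb, a factor that turns lysosome genes on, was lower at 21 h (−0.62) but near background. At 7 h 1 of 19 was higher, 4 when adjusted over the list alone (median 0.09, camera adjusted p = 0.110). Of these members 9 were higher at 14 h, 12 at 21 h beside 1 lower, and 14 at 30 h; adjusted over the list alone the higher members were 11, 13 and 14, beside 1 lower at 21 h and 1 at 30 h. Medians were 0.53, 0.99 and 1.36, with camera adjusted p = 4.05e-05, 1.09e-06 and 1.09e-06. In the list of nuclear condensation and late erythroid ubiquitin genes, the ubiquitin enzymes Ube2l6 (2.78) and Ube2h (2.71) rose by 30 h, and the chromatin genes Rbbp7 (2237 to 352, −2.66) and Kat2a (−2.39) and the actin regulator Rac1 (−1.54) fell. With 7 of 17 higher and 6 lower, 7 and 6 when adjusted over the list alone, the list did not pass (median 0.16, adjusted p = 0.911). At 21 h its median was 0.27 and its mean −0.02. Of 22 apoptosis regulators, Bcl2l1, the survival gene Bcl-xL, rose from 272 to 1371 (2.20) and Apaf1 by 0.99, while Bid, which promotes cell death, fell (−2.15). The other probe set of Bcl2l1 was not called at 30 h. The split was 5 higher and 1 lower, 5 and 1 when adjusted over the list alone (median 0.02, adjusted p = 0.597).

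Cytokine receptor signalling moved both ways. Csf2rb and Csf2rb2 rose, as did the survival kinase Pim1 (1575 to 4972) and the feedback inhibitor Cish (1.44), while Kit, the phosphatase Ptpn6 (−2.84), Akt1 (−1.41) and Socs2 (−1.17) were lower at 30 h. Epor, the receptor for erythropoietin, was lower at 3 h (584 to 373, −0.67) and stood at 0.02 at 30 h. Of 27 members 6 were higher and 5 lower at 30 h, 7 and 6 when adjusted over the list alone (median 0.20, adjusted p = 0.648). At 3 h 1 was higher and 3 lower, 2 and 5 when adjusted over the list alone (median −0.18, adjusted p = 0.0214; adjusted p = 0.208 with an estimated correlation; 0.117 without 0 h A and 0.0561 without 3 h C). In the list of immediate early and dissociation genes, which cells raise on handling, Jund and Ier2 were lower at 3 h. The split was 0 higher and 2 lower, 1 and 4 when adjusted over the list alone (median −0.13, adjusted p = 0.00680; adjusted p = 0.208 with an estimated correlation). At 30 h Klf6 (1.92), the mRNA decay factor Zfp36 (1.52) and Jund (1.25) were higher and Ier2 lower (−2.38). Of 20 members 8 were higher and 2 lower, 9 and 3 when adjusted over the list alone (median 0.48, adjusted p = 0.2).

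Heat shock and unfolded protein response genes were more often lower than higher at 30 h. The mitochondrial chaperones Hspa9 (2665 to 405, −2.72) and Hspd1 (4849 to 1446, −1.93) and the cytosolic Hsp90aa1 (−1.73) fell, whereas the stress factor Ddit3 (298 to 1522, 2.25) and the cochaperone Dnaja1 (1.76) rose. Of 24 members 2 were higher and 11 lower, 2 and 12 when adjusted over the list alone (median −0.54, adjusted p = 0.0154; adjusted p = 0.159 with an estimated correlation). At 21 h 2 were higher and 7 lower, 3 and 10 when adjusted over the list alone (adjusted p = 0.0351; adjusted p = 0.208 with an estimated correlation; 0.0565 without 0 h B and 0.0631 without 0 h C). Interferon response genes included B2m, the light chain of class I molecules (922 to 2588, 1.33), Igtp, an induced GTPase (1.78), and Irf9 (1.10), all higher, and Irf1, lower (−0.88) but near background. Of 21 members 5 were higher and 1 lower, 5 and 1 when adjusted over the list alone (median 0.10, adjusted p = 0.329).

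Glycolysis genes that fell by 30 h were Ldha, lactate dehydrogenase A (10199 to 1402, −3.19), the glucose transporter Slc2a1 (−2.63), Hk2 (−2.42) and Pgk1 (5366 to 1155, −2.39); Pfkm was higher (1.74). Of 16 members 1 was higher and 9 lower, 1 and 9 when adjusted over the list alone (median −1.27, adjusted p = 0.0584). In cholesterol and lipid synthesis, Fdft1, squalene synthase (323 to 1660, 2.20), Mvd (1.43) and Fdps (0.94) rose, and the fatty acid genes Elovl6 (−1.89) and Fasn (556 to 254) fell. Of 20 members 8 were higher and 3 lower, 9 and 3 when adjusted over the list alone (median 0.37, adjusted p = 0.247). At 7 h 1 was higher, 2 when adjusted over the list alone (median 0.22, adjusted p = 0.0287; adjusted p = 0.615 with an estimated correlation; 0.0741 without 0 h A, 0.0574 without 0 h B, 0.0621 without 7 h A and 0.183 without 7 h B).

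Of the 73 genes of the respiratory chain and ATP synthase, Cox6b2 (290 to 2289, 2.82) and Ndufa6 (382 to 1920, 2.18) rose by 30 h, and Ndufab1 (1449 to 344, −2.06), Atp5a1 (3539 to 1729, −1.28) and Ndufb5 (−1.15) fell. The split was 13 higher and 23 lower, 13 and 24 when adjusted over the list alone (median −0.03, adjusted p = 0.604). At 3 h 0 were called with limma, 0 when adjusted over the list alone, at a median of 0.08 (adjusted p = 0.0474; adjusted p = 0.615 with an estimated correlation; 0.0669 without 0 h B, 0.434 without 0 h C, 0.139 without 3 h B and 0.0650 without 3 h C). Of 20 histones, the linker H1f2 (2.48), H3c14 (2.10) and H2az2 (0.96) were higher at 30 h, and H2ax (−1.62), which marks DNA breaks, and H2az1 (−0.96) were lower. That made 3 and 2, the counts being 3 and 2 when adjusted over the list alone (median 0.02, adjusted p = 0.965).

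Among proteasome genes more were called lower than higher at 21 h and 30 h. By 30 h the assembly chaperone Psmg1 (704 to 70.5), the core subunits Psma3 (2474 to 614, −2.08) and Psmb4 (−1.29) and the lid subunit Psmd7 (1536 to 380) had fallen, while the ATPase Psmc2 rose (0.69). Of 42 members 5 were higher and 23 lower, 5 and 24 when adjusted over the list alone (median −0.57, adjusted p = 5.44e-05; adjusted p = 0.332 with an estimated correlation). At 21 h 6 were higher and 17 lower, 6 and 17 when adjusted over the list alone (median −0.32, adjusted p = 0.00122; adjusted p = 0.453 with an estimated correlation). Of 22 aminoacyl tRNA synthetases, which load amino acids onto transfer RNA, the mitochondrial Rars2 (−2.23) and Tars2 (−2.05) and the glycine enzyme Gars (926 to 227, −1.91) fell by 30 h, and Aars, for alanine, rose (552 to 1150, 0.99). At that time 3 were higher and 13 lower, 4 and 15 when adjusted over the list alone (median −0.82, adjusted p = 0.00640; adjusted p = 0.370 with an estimated correlation).

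In all, 45 of 160 list tests passed with the preset correlation, and 14 of them also with an estimated correlation. These 14 were heme biosynthesis at 7, 14, 21 and 30 h, autophagy at 14, 21 and 30 h, ribosome biogenesis at 14, 21 and 30 h, red cell membrane and skeleton at 14 and 21 h, globins at 30 h, and G1 cyclins and kinases at 30 h. The arrays 14 h A and 21 h A stood apart from their replicates. With both left out, Dmtn and the other members of the red cell membrane list gave 7 higher at 14 h and 7 at 21 h, mitosis gave 13 higher at 14 h, and ribosome biogenesis gave 21 and 23 lower at 14 h and 21 h. Other lists lost calls at 14 h: the proteasome gave 6 lower instead of 12 (14 when adjusted over the list alone), the respiratory chain 0 lower instead of 6 (7 when adjusted over the list alone), heat shock 3 lower instead of 5 (6 when adjusted over the list alone), tRNA synthetases also 3 instead of 5 (6 when adjusted over the list alone), apoptosis regulators 1 higher instead of 3 (3 when adjusted over the list alone) and interferon response 0 higher instead of 2 (2 when adjusted over the list alone). At 21 h DNA replication gave 18 lower instead of 23, mitosis 1 lower instead of 4, and neutrophil and macrophage markers 0 higher instead of 2 (25, 5 and 2 when adjusted over the list alone). Glycolysis gained, with 2 lower instead of 0 at 14 h and 6 instead of 3 at 21 h (0 and 3 when adjusted over the list alone). So did lists at 7 h, where the proteasome gave 5 lower instead of 2, tRNA synthetases 4 instead of 1, heat shock 3 instead of 1 and DNA replication 2 instead of 0 (4, 5, 3 and 1 when adjusted over the list alone), and cholesterol and lipid synthesis 3 higher instead of 1 (2 when adjusted over the list alone).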

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

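Of the tests compared here, those without the arrays 14 h A and 21 h A were chosen only after the result was seen; all other alternatives were set before. Of the named genes at 3 h and 30 h against 0 h under the alternatives, 4799 results were the same, 66 weaker, 39 stronger and 0 reversed. Of the lists 2743 were the same, 74 weaker, 63 stronger and 0 reversed. A result uncalled in both fits counted as the same whatever its sign, so direction was compared only where a call was involved. Changes of genes between neighbouring times were not in these counts. Of the 3314 probe sets called at 30 h against 0 h, 91.7% were also called in the values as deposited, 90.5% with median scaling, 97.0% with a constant of 1, 98.8% with a constant of 64, 96.3% without the intensity trend and 98.9% with array weights. With the dimmest 33.3% of probe sets left out 95.6% of the 3314 stayed called, and without 14 h A and 21 h A 98.7%. Counts over time ran from 3045 to 3531 against 3376, and at 30 h from 2815 to 3459.

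The counts at early times and between neighbouring times depended more on the choices, and the cause was not tested. At 3 h against 0 h, 132 became 202 with array weights, and 77 to 106 with 1 array left out. At 7 h against 0 h, 518 became 345 when only the arrays of the compared groups were used, which leaves fewer arrays for the variance. For 7 h against 3 h, 132 became 58 with median scaling, 63 without the intensity trend, 19 with only the compared groups, and 49 to 80 with 1 array left out. For 14 h against 7 h, 289 became 192 without 14 h A and 21 h A, 78 with only the compared groups, and 140 to 247 with 1 array left out. For 21 h against 14 h, 288 became 172 with median scaling, 180 without the intensity trend, 39 with only the compared groups, and 119 to 359 with 1 array left out. For 30 h against 21 h, 619 became 276 with only the compared groups, and 402 to 575 with 1 array left out. Of the 160 list tests 45 passed, and 31 of these 45 calls were lost with an estimated correlation. With fry 125 tests were the same, 28 stronger and 7 weaker.

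The labels give the same letters A, B and C at each time, so a replicate block was fitted. With it 161, 605, 1737, 2638 and 3351 probe sets were called at 3, 7, 14, 21 and 30 h against 0 h, 155, 341, 354 and 676 between neighbouring times, and 3417 over time. Deviations of arrays with the same letter from their time means correlated between −0.0918 and 0.205, above 0.1 in 3 of 45 pairs, and 16 of 18 arrays correlated best with an array of their own letter. Arrays of the same letter thus shared some variation, small in most pairs, which the main model left in its error. Replicate A had the lowest actin 3-prime to 5-prime ratio, a reading of RNA degradation, of its time at every time. The values were 1.19, 1.27, 1.30, 1.17, 0.968 and 1.07 from 0 h to 30 h. Its Gapdh ratio was also the lowest at every time but 3 h. RNA quality or labelling thus differed by letter. Whether this made the shared variation was not tested. With the block, among the named genes and the lists, calls were gained at 3 h by Csf2rb2 (1.29, adjusted p = 0.0145), Alas2 (0.91, adjusted p = 0.0324), Btg2 (0.92, adjusted p = 0.0328) and Mcpt1 (−1.12, adjusted p = 0.0368), at 30 h by Tfrc (0.71, adjusted p = 0.0281), and at 14 h by the proteasome list (adjusted p = 0.0496), while the list of stem and progenitor regulators lost its call at 14 h (adjusted p = 0.0622). All other counts were made without the block.

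Signal over background set a further limit. The control probe sets for absent transcripts reached 52.9, and genes with means under about 50 at all times, among them Cd34 and Hoxa10, were not resolved from it. For these a lack of a call does not bear on whether the transcript changed.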

Other observations

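The tests of values high or low at 14 h, of the actin ratio, of the left-out 3 h arrays and of the immediate early list were chosen only after the result was seen. So were the genes named for such values. Several transcripts were higher at 14 h than at 0 h and lower at 30 h than at 14 h. These comparisons do not show when between 0 h and 30 h a transcript turned. Of 31 mitosis genes, 0 were called from 7 h to 14 h or from 14 h to 21 h, and 29 were lower from 21 h to 30 h. Cdc6, a licensing factor of DNA replication, rose from 494 to 1667 by 14 h (1.76, SE 0.11) and fell to 185 by 30 h (−3.02 against 14 h). Noct, a circadian phosphatase gene, went from 355 to 1222 and back to 338, Cenpa, the histone of centromeres, from 248 to 628 and then 200, and the platelet gene Gp9 from 30.8 to 118 and then 25.1. The spindle gene Nusap1 (1.43, then −1.50), the centrosome gene Cep250 (1.31, then −2.65), Septin4 (1.72, then −2.59) and Ubac1 (1.58, then −1.42) had the same shape. In total 95 probe sets for 83 genes were higher at 14 h and then lower at 30 h than at 14 h. By the brightest probe set of each of 8251 genes there were 76 such genes. A Fisher test found among them 11 of 31 mitosis genes (adjusted p = 4.47e-14), 3 of 16 erythroid transcription factors (adjusted p = 0.00617) and 3 of 35 DNA replication genes (adjusted p = 0.0424). This test treats genes as independent, although members of a list can move together, and the shape was chosen after the results were seen. Its p values are therefore too small and give no separate support. Camera with an estimated correlation gave adjusted p = 0.514 for mitosis at 14 h.

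The opposite shape was that of the metallothioneins, which bind zinc and copper. Mt2 fell from 11534 to 2586 by 14 h (−2.33, SE 0.22) and stood at 17134 at 30 h (2.59 against 14 h), and Mt1 went from 8258 to 2839 and then 15448. Mnt (−1.59, then 1.34), Tex264, which clears endoplasmic reticulum (−1.31, then 1.64), the factor Nfic (−1.32, then 1.21), the cytoskeletal Macf1 (301, 121, then 279) and H2-K2, a class I gene read by an uncertain probe set (−1.15, then 2.40), were further examples among 58 probe sets for 50 genes. The signal of Mnt had been lower still at 3 h, so its low point was not at 14 h. A simulation with no change after 14 h gave 0 such calls. With no true change in any probe set from 14 h to 30 h, that outcome was close to fixed in advance. The 0 therefore does not measure how many calls of these shapes are false in the data. With 1 array left out, peaks ran from 58 (without 14 h C, with 63 without 30 h B) to 82, valleys from 38 (without 0 h C) to 61, and mitosis genes among the peaks from 7 (without 14 h B) to 11. Median scaling gave 51 peaks, 50 valleys and 7 mitosis genes.

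The arrays 14 h A and 21 h A stood apart from B and C of their times. A culture further along the time course could explain it: the difference of 14 h A correlated at 0.283 with the step from 7 h to 21 h, and that of 21 h A at 0.277 with the step from 14 h to 30 h. Both lay between the bounds of 0.1 and 0.3, which leaves the explanation undecided. RNA degradation might also set arrays apart, but the actin 3-prime to 5-prime ratio was 1.17 and 0.968, beside a median of 1.42 in the other 16, which argues against it. Deviations of 14 h A and 21 h A from their time means correlated with each other at 0.205, the highest value among the 45 same-letter pairs. Replicate A had the lowest actin ratio of its time at every time, so a low ratio was not particular to 14 h A and 21 h A. What these arrays shared was not tested.

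Of 38 probe sets lower at 3 h, 6 were higher again at 7 h than at 3 h. These were Pim1, the survival kinase (1575, 575, 1615), Cbfa2t3 (351, 57.1, 137), Epor (584, 373, 685), Jund (1366, 281, 994), Scd2 and Cdc42se1. The return of Jund was lost without 3 h B, 3 h C or 7 h A. Without 3 h A, B or C there were 4, 4 and 3 such probe sets, and the 4 without B included Zfp94, which is not among the 6. Noise of the 3 h arrays could produce such a return, and the probe sets picked only as lower without C, A or B rose from that array to 7 h by a median of 0.376, 0.226 and 0.207, with lower quartiles of −0.110, −0.195 and −0.177, so it stays open for the 6 as a whole. In all 4, 4 and 3 picked as lower and higher again without A, B or C the left-out array lay below the means of 0 h and 7 h. Lower quartiles of the rise to 7 h were 1.19, 0.730 and 0.837. Cbfa2t3, Epor and Pim1 were picked in every round and rose by 3.80 to 8.12 errors of the difference. Within a round the left-out array took no part in the picking, so there these rises argue against noise of that array alone. Naming these genes for being picked in every round drew on all 3 h arrays, so that choice was not held out. The 0 h and 7 h arrays served both to pick and to compare, so noise in them was not held out. Zfp94 (picked without B) rose by 0.942 errors of the difference and Jund (picked without A) by 2.49, and both stay open. Scd2 and Cdc42se1 were picked in none and stay open as well. A general fall from handling might also produce such a return. Of 20 immediate early genes 2 were called lower at 3 h, 4 when adjusted over the list alone. Camera put that list (adjusted p = 0.00680) and cytokine receptor signalling (adjusted p = 0.0214) lower, both at adjusted p = 0.208 with an estimated correlation. A fall from handling therefore stays open too. A biological explanation was not tested.

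Of 31 mitosis genes 11 were called higher at 14 h, 13 when adjusted over the list alone (camera adjusted p = 0.000110; adjusted p = 0.514 with an estimated correlation), and 27 lower at 30 h, 27 when adjusted over the list alone. Noise in 14 h A could explain the rise, but the list median at 14 h was 0.579 without that array and 0.507 with it. Scaling between arrays might also explain it, but the lowest median under the other scalings was 0.456. Both values argue against these explanations of the list median. A biological explanation was not tested.

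As a check on chance, the 6 arrays of each comparison were split in all ways into 3 and 3. For 3, 7, 14, 21 and 30 h against 0 h, 1 of 10 splits, the real one, called as many, with 132, 518, 1655, 2571 and 3314 calls beside a highest other of 0, 1, 0, 0 and 1. For 7 h against 3 h, 14 h against 7 h, 21 h against 14 h and 30 h against 21 h it was also 1 of 10, with 132, 289, 288 and 619 calls beside 0, 3, 3 and 3. A set of 10 splits cannot give a share under 0.05. Every other split mixed the compared times in each group, so their real difference entered the error and few calls were bound to result. The counts of the other splits thus do not measure how many calls arise by chance. Over time it was 1 of 100 regroupings, with 3376 calls beside a highest other of 920, and these regroupings mixed the times as well.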
